A study of Rattus rattus with 8 samples.

How the data were processed

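Epithelium was shaken off proximal colon tissue after incubation with a chelating agent, and messenger RNA selected by its poly(A) tail was sequenced as a directional, paired-end library, per the labels' protocols. The 8 samples are 4 WKY and 4 SHR, by their titles. The labels name the organism as Rattus rattus, while the deposited gene identifiers carry the Ensembl prefix of the brown rat, to which both strains belong.

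FastQC, Trimmomatic and STAR are named in the submitters' processing notes, without version or role. The genome build, annotation, counting tool and test are not given in the sources used here. The value per gene and library was taken as FPKM, a unit that no file header or label names. It was inferred from the deposited values, because value times a length per gene summed to 982968 to 1017515 per library, while the plain sums differed more. That length was itself computed from the authors' mean CPM and these values, so the size of the total follows by construction. Only the evenness between libraries speaks for the unit. The deposited table also holds the mean CPM of each strain, a log2 fold change, a p-value and a q-value for SHR against WKY, per the file headers. The authors' q-values equal Benjamini-Hochberg values of their p-values over the 11762 genes, and their log2 fold change is close to the log2 ratio of the mean CPM columns (median difference 0.00119). The deposited list of 611 symbols holds p-values up to 0.0864 and log2 fold changes of at least 1 in size. The remaining tables repeat rows of the main table and were not used here.

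The files hold FPKM and no counts, so the count test written before the data were examined was replaced by the test fixed for normalized values. Genes with at least 1 FPKM in at least 4 libraries were kept (11069 of 11762). Values were taken as log2(FPKM + 1), a scale that understates changes of genes at low levels, and tested with limma 3.58.1 in R 4.3.3 (linear model on strain, empirical Bayes with trend and robust settings, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 fold changes are SHR over WKY with limma's standard error, and means are given with the SD of 4 libraries. Figures were drawn with matplotlib 3.10.9. The 35 gene lists were fixed before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with 1 row per symbol (that of highest mean). Of the 735 distinct list symbols, 227 had no row under that name and were not analysed here.

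The rule for named genes was also fixed beforehand. It takes the 8 largest and 8 smallest log2 fold changes among genes past the threshold whose strains do not overlap and whose mean is at least 1 FPKM, leaving out identifiers without a gene symbol. It adds the 4 most significant remaining genes, up to 4 called members of each list that passed camera or had 3 called members, and the genes of the renin-angiotensin and SHR trait lists. A few genes that the rule takes are not reported here.

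On simulated data for SHR against WKY, with 200 of the 11069 genes changed, the test recovered 43.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold, and 5 of 155 calls were false. The list step called the 1 list that had been shifted and 1 that had not. The simulation drew noise independently for each gene and changed no genes of the lowest levels. Genes of the real libraries can vary together, so these rates may not hold for them, least of all for lists.

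Reads per library cannot be recovered from the values, which are rounded to 2 decimals and divided by lengths that differ per gene, so no interval for counting error can be given. Low values were inspected for this. An effective length per gene was computed as the sum of the authors' mean CPM over the sum of mean FPKM of both strains. Of the listed genes 55 were at 0 in at least 1 library, among them genes that nearly every cell expresses, and a listed 0 can be a failed estimate. There were 62 rows in 27 sets with identical values in all libraries, where reads of identical copies seem to be divided evenly. Strand use in counting is not given in the sources used here, so overlapping genes cannot be told apart. No batch or date was given in the labels, and no pair of libraries held identical values.

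The alternatives were other pseudocounts (0.1 and 5), no filter, quantile normalization, median centring, the replicate number as a block, leaving out each library, 2-fold thresholds, the authors' q-values, and for lists an estimated correlation, fry, and leaving out genes below the median level. The exact permutation test of list scores was added after seeing the data, as were the removal of a length trend (lowess per library), leaving out genes under 200 bases, collapsing identical rows, and scaling without the 13 mitochondrial genes. Gene order was taken from the black rat assembly Rrattus_CSIRO_v1, in which 8892 of the 11069 tested genes were found by symbol, and no coordinate from it is used.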

Results

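RNA was sequenced from epithelium released from the proximal colon of 2 inbred rat strains, with 4 libraries labelled WKY and 4 labelled SHR. The spontaneously hypertensive rat (SHR) develops high blood pressure with age, and the Wistar-Kyoto rat (WKY) is the strain commonly used as its normotensive control. The labels number the libraries 1 to 4 within each strain and do not say whether each came from a separate animal, so p-values measure the spread between these libraries. The deposited table lists 11762 genes with an FPKM value per library. The number of reads behind a value is unknown. The FPKM values summed to between 882295 (SHR replicate 3) and 1066833 (WKY replicate 4) per library, and between 10708 and 11124 genes reached 1 FPKM.

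The libraries separated by strain before any gene was tested. The first principal component of the 11069 tested genes held 49.7% of the variance, with the WKY libraries between -25.77 and -17.12 and the SHR libraries between 19.66 and 27.65. Spearman correlations across genes were 0.969 to 0.987 within a strain and 0.949 to 0.965 between strains. Genes are not independent replicates, so these correlations carry no p-value. Along the second component, with 18.1% of the variance, WKY replicate 3 lay lowest at -17.68 and SHR replicate 4 highest at 24.17.

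**Figure D1:**
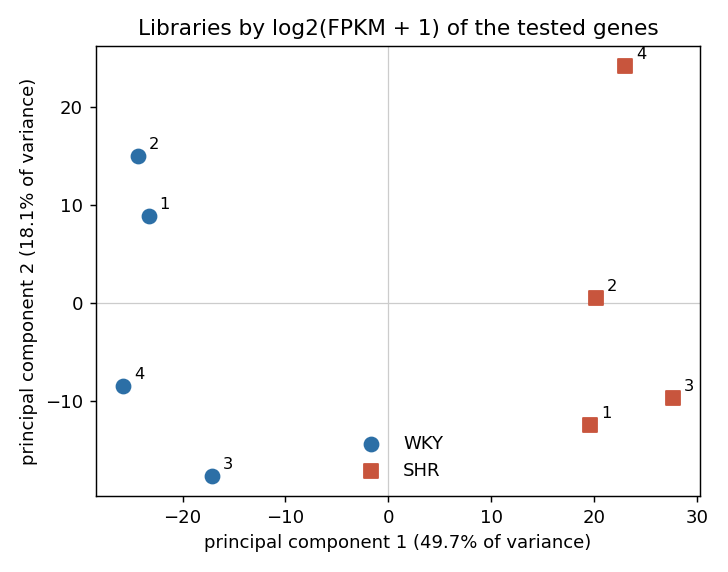
Each point is a library, placed by the first 2 principal components of log2(FPKM + 1) over the 11069 tested genes, with the replicate number beside it. The first component (49.7% of the variance) parts the 4 WKY libraries (circles, all below -17) from the 4 SHR libraries (squares, all above 19).

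The comparison of SHR with WKY asked which genes the colonic epithelium of the hypertensive strain expresses at another level. Several genes were at or near 0 in 1 strain and abundant in the other. The carbonyl reductase genes Cbr1 (ENSRNOG00000047848) and Cbr3 (ENSRNOG00000001701), whose enzymes reduce ketones and aldehydes, were listed at 0 in all WKY libraries. In SHR replicates 1 to 4 the values were 34.48, 33.5, 32.4 and 25.79 FPKM for Cbr1 and 65.45, 62.82, 45.13 and 60.72 FPKM for Cbr3. Setd4 (ENSRNOG00000001699), a gene for a lysine methyltransferase, was listed at 0.03, 0.03, 0.03 and 0 FPKM in WKY and at 13.29, 14.92, 12.06 and 15.8 FPKM in SHR. In the opposite direction, Alpi, which encodes intestinal alkaline phosphatase of the brush border, was listed at 8.35, 9.04, 19.31 and 15.68 FPKM in WKY and at 0, 0.02, 0 and 0 FPKM in SHR. These 4 genes passed limma's test with Benjamini-Hochberg adjusted p of 4.58e-11, 2.51e-11, 2.94e-10 and 4.00e-07 for Cbr1, Cbr3, Setd4 and Alpi. The same holds for Hsp90aa1 (adjusted p = 0.00157), the gene of a cytosolic chaperone made by nearly every cell. It was listed at 0 in all WKY libraries and at 5.9, 13.79, 14.77 and 36.32 FPKM in SHR, so a listed 0 may not be a measured absence. No fold change is given for a group at 0.

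Among the other genes with the largest rises in SHR, Ephx2 encodes soluble epoxide hydrolase, which turns epoxides of arachidonic acid into diols. Its mean was 2.79 ± 0.154 FPKM in WKY and 50.04 ± 6.68 FPKM in SHR (SD, n = 4 each), a log2 fold change of 3.74 ± 0.12 (SE, limma adjusted p = 4.53e-10). The class I major histocompatibility gene RT1-CE6 went from 1.21 ± 0.481 to 142.1 ± 23.0 FPKM, a log2 fold change of 6.03 ± 0.16. Hmgb2, which encodes a chromatin protein of dividing cells, rose by 3.58 ± 0.21 on the log2 scale. Its WKY level of 0.875 ± 0.521 FPKM is low and rests on an effective length of 401 bases, so that level is uncertain. The butyrophilin-like gene Btnl7 rose by 3.36 ± 0.23 for the identifier ENSRNOG00000000446, and less, by 1.86, for its other listed identifier ENSRNOG00000050170. The 4 most significant of the remaining genes were Fam78b (from 0.522 ± 0.186 to 14.66 ± 2.60 FPKM), Tmem14a (from 3.12 ± 0.567 to 33.26 ± 3.32 FPKM), the palmitoyl thioesterase gene Ppt2 (from 20.998 ± 3.07 to 116.02 ± 14.1 FPKM) and Zp2, known for the egg coat, at 0.070 ± 0.029 FPKM in WKY and 3.73 ± 0.432 FPKM in SHR. RT1 and butyrophilin-like genes have close relatives among which reads can be divided, so their levels are uncertain.

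Among the genes with the largest falls, Pigz, which encodes a mannosyltransferase of glycosylphosphatidylinositol anchors, went from 19.7 ± 4.60 FPKM in WKY to 0.060 ± 0.057 FPKM in SHR (log2 fold change -4.27 ± 0.15, adjusted p = 1.23e-09). It is listed under 2 identifiers with identical values in every library. Acsbg1, an acyl-CoA synthetase gene, fell from 41.5 ± 18.9 to 1.998 ± 0.387 FPKM and the carboxylesterase gene Ces1d from 10.86 ± 3.31 to 0.810 ± 0.247 FPKM. Serhl2 fell from 11.6 ± 1.36 to 1.03 ± 0.116 FPKM, and the interferon-induced Ifi44l from 10.3 ± 2.83 to 0.943 ± 0.223 FPKM. The class I pseudogene RT1-CE9-ps1 fell by 3.63 ± 0.21 on the log2 scale and the class II gene RT1-Ba fell by 3.17 ± 0.22.

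**Figure D2:**
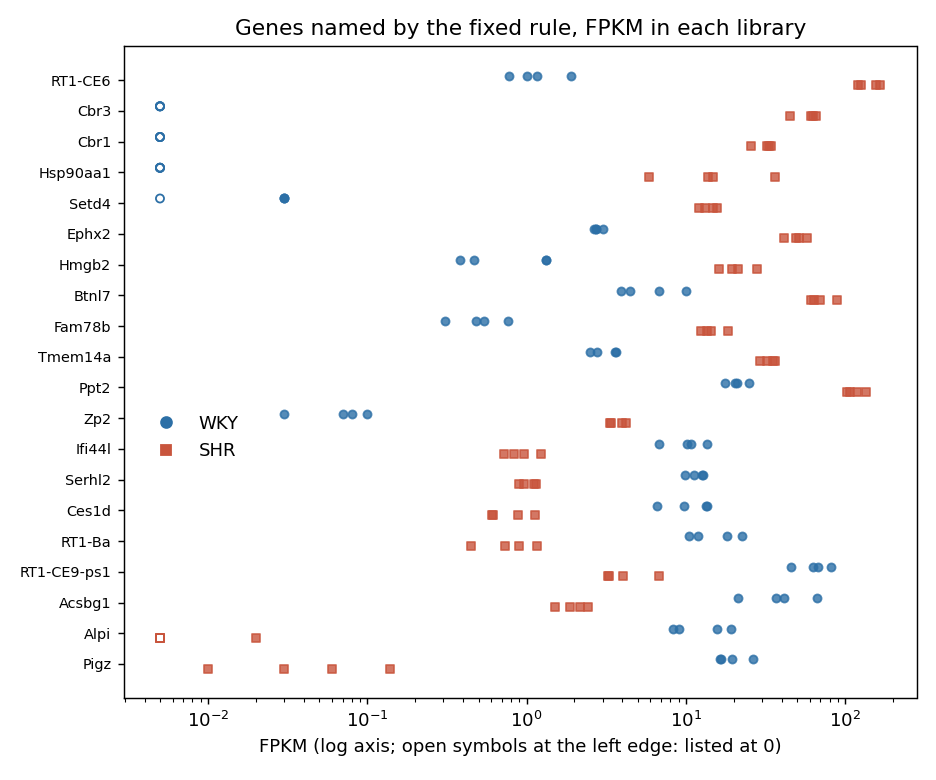
FPKM in each WKY library (circles) and SHR library (squares) on a log axis, for the 20 genes that the rule fixed beforehand named by size of change or by significance; open symbols at the left edge mark values listed at 0. The symbols of the 2 strains do not overlap for any of these genes, because the rule took only genes without overlap. Cbr1, Cbr3 and Hsp90aa1 are at 0 in all 4 WKY libraries.

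Over all 11069 tested genes, 376 were higher and 828 lower in SHR at an adjusted p under 0.05 (limma on log2(FPKM + 1)), and 64 of the first and 143 of the second differed by at least 2-fold on that scale. All 4 SHR values lay above all 4 WKY values for 584 genes and below them for 1199, together 16.1% of the tested genes, where chance gives 2.86%. The split between higher and lower genes moved with the scaling. It was 642 higher and 644 lower after quantile normalization, 541 and 714 after each library was centred on its median gene, and 564 and 639 after a trend with gene length was removed from each library, which centres the libraries too, against a median log2 fold change of -0.07 over all genes as deposited. Leaving out 1 library gave 191 to 550 higher and 440 to 1126 lower genes. The higher count fell by more than 1.5 times without WKY replicate 1 (237), WKY replicate 4 (209), SHR replicate 2 (205) or SHR replicate 3 (191), and the lower count without WKY replicate 1 (522), WKY replicate 2 (521), WKY replicate 4 (440) or SHR replicate 3 (497).

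Of 35 gene lists fixed beforehand, 30 had at least 3 tested members, and 12 of these passed camera with a preset correlation of 0.01, 7 lower and 5 higher in SHR. With a correlation estimated from the data 0 of the 12 passed, so each list below is given with its estimated-correlation p. Adjusted p-values of lists are Benjamini-Hochberg values over the 30 lists.

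The list of mitosis and S phase was lower in SHR, while Hmgb2, which is not in it, rose from an uncertain low level in WKY. Of its members, 14 of 30 tested fell, 0 rose and 16 did not pass, with a median log2 fold change of -0.57 and a negative value in all 30. The count was 23 lower and 0 higher adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, fell from 36.0 ± 7.77 to 20.6 ± 3.61 FPKM (adjusted p = 0.0125). Mcm2, a subunit of the replicative helicase, fell from 10.54 ± 1.76 to 6.29 ± 0.846 FPKM. Birc5 and Aurka fell by 0.76 ± 0.17 and 0.68 ± 0.16 on the log2 scale. The list's adjusted p was 8.80e-08 with the preset correlation, and adjusted p = 0.534 with an estimated correlation and 0.0692 with fry. The mean of its members overlapped between the strains, since WKY replicate 3 lay at -0.15 and SHR replicate 4 at -0.05, relative to the mean of all libraries.

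Markers of secretory cells were also lower. Of 17 tested goblet cell markers, 7 fell and 0 rose (11 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -0.59. Clca1, a protein secreted with mucus, fell from 393.0 ± 83.7 to 111.8 ± 10.9 FPKM, a log2 fold change of -1.79 ± 0.15 (adjusted p = 7.00e-06). Agr2, a disulfide isomerase needed for mucin folding, fell from 1368 ± 176.1 to 731.6 ± 147.7 FPKM, and the mucus protein gene Fcgbp from 200.6 ± 28.9 to 111.2 ± 10.3 FPKM. Of 11 enteroendocrine markers, 4 fell and 0 rose, and the count was the same adjusted over the list alone. The hormone gene Cck fell from 14.6 ± 1.83 to 2.20 ± 0.911 FPKM (adjusted p = 9.37e-06), and Neurod1, a transcription factor of these cells, from 1.48 ± 0.619 to 0.423 ± 0.102 FPKM. The lists had camera adjusted p of 0.000274 (goblet) and 0.000833 (enteroendocrine) with the preset correlation, and adjusted p = 0.495 for both with an estimated correlation. The enteroendocrine call ended when genes below the median level were left out (adjusted p = 0.0892).

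In the list of the unfolded protein response, which serves folding in the endoplasmic reticulum, 4 of 21 members fell and 0 rose (11 lower and 0 higher adjusted over the list alone). All 21 had a negative log2 fold change, with a median of -0.38, and Ern2 is a member of both this list and the goblet cell markers, which were lower too. The disulfide isomerase gene Pdia6 fell from 171.4 ± 16.0 to 107.1 ± 21.7 FPKM, Sdf2l1 by 0.76 ± 0.12 on the log2 scale, and Asns, which encodes asparagine synthetase, by 0.81 ± 0.16. Camera gave an adjusted p of 0.00023 with the preset correlation, and adjusted p = 0.495 with an estimated correlation.

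Transcripts of lymphocytes and of antigen presentation were lower in SHR. Of 11 markers of T and natural killer cells, which can stay in a preparation of epithelium, 5 fell, 0 rose and all 11 had a negative log2 fold change, with a median of -1.23 (10 lower and 0 higher adjusted over the list alone). The granzyme gene Gzma was at 46.1 ± 25.1 FPKM in WKY and 7.21 ± 2.65 FPKM in SHR (adjusted p = 0.0073), Gzmb at 7.42 ± 2.45 and 1.36 ± 0.855 FPKM, and Cd3g of the T cell receptor complex at 7.598 ± 3.31 and 2.12 ± 0.770 FPKM. The camera adjusted p was 1.39e-05, and adjusted p = 0.534 with an estimated correlation. Mean levels of the list spread widely among the WKY libraries, from -0.29 in replicate 2 to 1.40 in replicate 3. Of 7 class II presentation genes, 5 fell and 0 rose (6 lower and 0 higher adjusted over the list alone), with a median of -1.19. RT1-Bb went from 7.55 ± 3.62 to 1.12 ± 0.341 FPKM. RT1-Da (from 14.30 ± 5.16 to 6.77 ± 2.31 FPKM) and RT1-Db1 (from 8.33 ± 4.12 to 2.95 ± 1.06 FPKM) fell with adjusted p of 0.0358 and 0.0258, and their calls ended under several alternatives. The class II list had an adjusted p of 0.000666, and adjusted p = 0.495 with an estimated correlation, or 0.315 when genes below the median level were left out. The class II genes named are RT1 genes, among whose close relatives reads can be divided, so their levels are uncertain. A difference in read assignment between the strains cannot be told apart from lower expression here.

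Interferon-stimulated genes went both ways. Of 33 tested members, 10 fell and 2 rose, with a median of -0.46 (16 lower and 2 higher adjusted over the list alone). Besides Ifi44l, the immunoproteasome gene Psmb9 fell from 159.99 ± 45.9 to 70.6 ± 6.56 FPKM and the transcription factor gene Irf9 from 26.2 ± 7.00 to 13.3 ± 1.14 FPKM. Ifit1, an RNA-binding antiviral protein, rose from 0.048 ± 0.036 to 2.87 ± 0.899 FPKM (adjusted p = 7.26e-06). Camera gave an adjusted p of 0.00131, and adjusted p = 0.628 with an estimated correlation. WKY replicate 2 stood highest for this list at 0.90, with the other WKY libraries between -0.05 and 0.16, and without that library the adjusted p was 0.0338. The markers of T and natural killer cells were at their lowest WKY level in the same replicate.

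**Figure D3:**
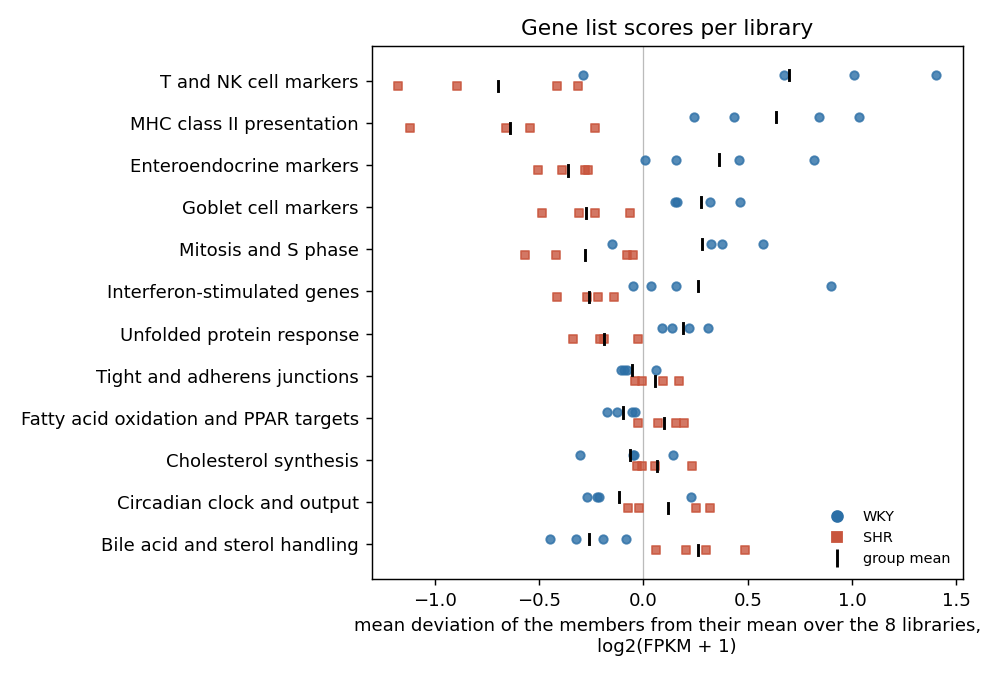
For each of the 12 lists that passed camera with the preset correlation, points give the mean deviation of the list's members in each WKY (circles) and SHR library (squares) from their mean over the 8 libraries, in log2(FPKM + 1), and bars give group means. The strains do not overlap for 8 of the 12 lists, and overlap for mitosis and S phase, cholesterol synthesis, tight and adherens junctions and the circadian clock.

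Lists of lipid handling were higher in SHR by camera with the preset correlation. Of 9 genes of bile acid and sterol handling, 3 rose and 0 fell (5 higher and 0 lower adjusted over the list alone), with a median of 0.39. Slc51a, a subunit of the basolateral bile acid exporter, rose from 60.2 ± 2.30 to 92.0 ± 17.0 FPKM (adjusted p = 0.014), the vitamin D receptor gene Vdr from 99.6 ± 6.87 to 148.6 ± 19.7 FPKM, and the bile acid importer gene Slc10a2 from 0.378 ± 0.319 to 3.16 ± 2.07 FPKM. The adjusted p was 0.00107, and adjusted p = 0.382 with an estimated correlation and 0.0147 with fry. In the list of fatty acid oxidation and PPAR targets 2 of 21 rose and 0 fell (4 higher and 0 lower adjusted over the list alone), with a median of 0.10. Both are fatty acid binding protein genes of the intestine, Fabp1 (from 1833 ± 244.9 to 3281 ± 535.3 FPKM, adjusted p = 0.00402) and Fabp2 (from 131.7 ± 51.8 to 236.9 ± 36.9 FPKM, adjusted p = 0.0395, a call lost in 7 of 8 fits without a library). None of the called members is an enzyme of fatty acid oxidation. The list had an adjusted p of 0.00253, and adjusted p = 0.495 with an estimated correlation and 0.0692 with fry. In cholesterol synthesis 5 of 22 rose and 0 fell (5 higher and 1 lower adjusted over the list alone), with a median of 0.16. Among them, the squalene synthase gene Fdft1 rose from 50.5 ± 8.68 to 72.2 ± 4.53 FPKM. The adjusted p was 0.00107, and adjusted p = 0.534 with an estimated correlation and 0.2 with fry. The mean of the cholesterol list's members overlapped between the strains, with WKY replicate 2 at 0.143 and SHR replicate 3 at -0.033.

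Of 23 genes of tight and adherens junctions 4 rose and 0 fell (6 higher and 1 lower adjusted over the list alone), but the median was 0.02. Nectin2 rose from 40.3 ± 2.90 to 64.8 ± 13.2 FPKM and the tricellulin gene Marveld2 from 14.8 ± 0.986 to 20.5 ± 2.32 FPKM, and Marveld3 and F11r rose by 0.57 ± 0.13 and 0.44 ± 0.12 on the log2 scale. Of 8 fits without a library, the call was lost in 6 for F11r, 4 for Marveld2 and 1 for Marveld3. The adjusted p was 0.02, and adjusted p = 0.495 with an estimated correlation, or 0.103 with the length trend removed. Of 15 circadian genes 1 rose and 1 fell (4 higher and 1 lower adjusted over the list alone), with a median of 0.24. Per2, a repressor of the clock, rose from 2.33 ± 0.611 to 4.49 ± 1.48 FPKM (adjusted p = 0.0493, lost in 6 of 8 fits without a library), and Nfil3 fell from 21.2 ± 3.02 to 9.49 ± 2.19 FPKM (adjusted p = 0.00073). The circadian list's adjusted p was 0.0211, and adjusted p = 0.534 with an estimated correlation. Its call ended under 8 alternatives, among them leaving out WKY replicate 1 (0.0819), WKY replicate 2 (0.0881) or SHR replicate 3 (0.0972), and the time of day of sampling is not given in the sources used here.

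Genes with a place in blood pressure control were examined as lists of their own. In the renin-angiotensin system 2 of 10 members rose and 0 fell, over all genes and adjusted over the list alone. Ace, which makes angiotensin II, rose from 7.58 ± 2.85 to 34.6 ± 6.90 FPKM, a log2 fold change of 2.10 ± 0.25 (adjusted p = 0.000594). Prcp, a carboxypeptidase that cleaves angiotensin II, rose from 10.82 ± 0.534 to 16.2 ± 3.40 FPKM (adjusted p = 0.0299, lost in 6 of 8 fits without a library). The list did not pass camera (adjusted p = 0.431). Of 9 tested genes put forward earlier for traits of SHR, 1 rose and 2 fell, over all genes and adjusted over the list alone, and the list did not pass (adjusted p = 0.833). The 1 that rose was Ephx2. Endog, a mitochondrial nuclease linked to heart mass in rats, fell from 20.6 ± 3.66 to 4.37 ± 1.22 FPKM (adjusted p = 7.36e-06). Gstm1, a glutathione transferase, fell from 15.9 ± 3.20 to 3.63 ± 1.32 FPKM (adjusted p = 5.17e-05). Rgs2 was at 18.5 ± 5.15 and 12.4 ± 6.37 FPKM and did not pass (adjusted p = 0.206). Cd36, the fatty acid transporter that carries a known defect in SHR, reached 1 FPKM in too few libraries to be tested, with 0.5, 1.48, 1.44 and 1.65 FPKM in WKY and 0.14, 0.21, 0.04 and 0.3 FPKM in SHR.

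Lists that did not pass still held single genes that changed. In antimicrobial and barrier secretions 1 of 14 rose and 5 fell (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.833). The hydrogen peroxide source Duox2 rose from 10.7 ± 3.67 to 22.5 ± 4.30 FPKM, and Itln1 and Lcn2, a lectin and an iron-trapping protein, fell by 1.05 ± 0.19 and 1.13 ± 0.18 on the log2 scale. In xenobiotic metabolism and antioxidant response 1 of 28 rose and 6 fell (same counts adjusted over the list alone, adjusted p = 0.277), among them the heme oxygenase gene Hmox1, from 10.51 ± 2.56 to 3.16 ± 1.12 FPKM. In ion and water transport 1 of 26 rose and 3 fell (2 and 4 adjusted over the list alone, adjusted p = 0.431). The water channel gene Aqp1 fell by 1.01 ± 0.18 and the chloride channel gene Ano1 by 0.90 ± 0.16 on the log2 scale, and the anion exchanger gene Slc4a2 rose by 0.47 ± 0.13. In inflammatory cytokines and NF-kB targets 3 of 18 rose and 4 fell (5 and 5 adjusted over the list alone, adjusted p = 0.701), with Tnfaip3, a brake on NF-kB, up by 0.74 ± 0.16 and Il18 down from 90.5 ± 23.8 to 37.96 ± 4.96 FPKM. Among stem cell and Wnt targets 1 of 10 rose and 3 fell (1 and 5 adjusted over the list alone, adjusted p = 0.275). Smoc2, Cd44 and Ephb3 fell by 0.79 ± 0.16, 0.83 ± 0.15 and 0.62 ± 0.15 on the log2 scale, and Cdx1 rose by 0.46 ± 0.12.

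The other lists had few called members. Short-chain fatty acid uptake, sensing and ketogenesis had 2 of 14 lower and 0 higher (adjusted p = 0.507), and serotonin and catecholamine handling 2 of 8 lower and 0 higher (adjusted p = 0.4). Heat shock and early response, which reads tissue handling, had 1 of 23 higher and 2 lower (adjusted p = 0.814). Hypoxia and glycolysis had 1 of 21 higher and 1 lower (adjusted p = 0.986), nuclear-encoded oxidative phosphorylation 0 of 30 higher and 1 lower (adjusted p = 0.132), and distal colon Hox genes 0 of 3 higher and 1 lower (adjusted p = 0.4). Adjusted over the list alone, the counts of higher and lower genes were 0 and 2, 0 and 3, 1 and 4, 1 and 1, 0 and 1, and 0 and 1 in the same order. Of the 30 oxidative phosphorylation members 29 had a negative log2 fold change, with a median of -0.125. A nearly uniform sign is thus not particular to the lists that passed.

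Among the lists of other cell types, markers of absorptive colonocytes had 1 of 21 higher and 2 lower, with a median of 0.14 and adjusted p = 0.202. Dpp4, a brush border peptidase, fell from 8.69 ± 1.98 to 4.58 ± 0.775 FPKM and the keratin gene Krt18 from 153.6 ± 16.8 to 107.7 ± 7.14 FPKM, while Tmigd1 rose by 0.35 ± 0.10 on the log2 scale. Tuft cell markers had 0 of 10 called (adjusted p = 0.768, median -0.02). Smooth muscle (1 of 5 higher, adjusted p = 0.202), fibroblast (1 of 3 higher, adjusted p = 0.232) and macrophage and dendritic cell markers (1 of 7 higher, adjusted p = 0.777) did not pass. Their median log2 fold changes were 0.05, 0.44 and -0.53 in that order. Of the 7 macrophage and dendritic cell markers 5 had a negative value. Adjusted over the list alone, the counts of higher and lower genes were 3 and 4 for colonocytes, 0 and 0 for tuft cells, 1 and 0 for smooth muscle, 2 and 1 for fibroblasts and 1 and 0 for macrophages and dendritic cells. Of the 5 lists with under 3 tested members, granulocyte and mast cells had 1 of 2 lower, endothelium 1 of 1 lower and erythroid cells 0 of 2, and B and plasma cells and enteric neurons and glia had 0 tested. The test's direction differed in sign from the median, the mean or both in 7 lists, none of them called. These were ion and water transport, the renin-angiotensin system, inflammatory cytokines and NF-kB targets, hypoxia and glycolysis, colonocytes, tuft cells and fibroblasts.

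With 4 libraries per strain and 6 library checks, a single check cannot pass the multiple-test adjustment, so the exact p-values below decide nothing on their own. Mitochondrial genes made up 15.45 ± 2.72% of the length-weighted signal in WKY and 16.4 ± 2.20% in SHR (SD, n = 4 each, two-sided exact permutation p = 0.657). Genes of ribosomal proteins made up 2.87 ± 0.322% and 2.40 ± 0.259% (exact permutation p = 0.114). The number of genes at 1 FPKM or more was 11040 ± 56.6 in WKY and 10840 ± 99.9 in SHR (exact permutation p = 0.0286, the smallest 4 against 4 allows, adjusted 0.171), with 11005 to 11124 in the WKY libraries and 10708 to 10952 in the SHR libraries. The median log2 fold change rose with the effective length of the gene, from -0.23 below 200 bases (159 genes) to 0.06 above 4000 bases (1505 genes). The difference between long genes (over 4000 bases) and short genes (under 1000 bases) was -0.116 ± 0.138 in WKY and 0.104 ± 0.189 in SHR libraries (exact permutation p = 0.114).

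**Figure D4:**
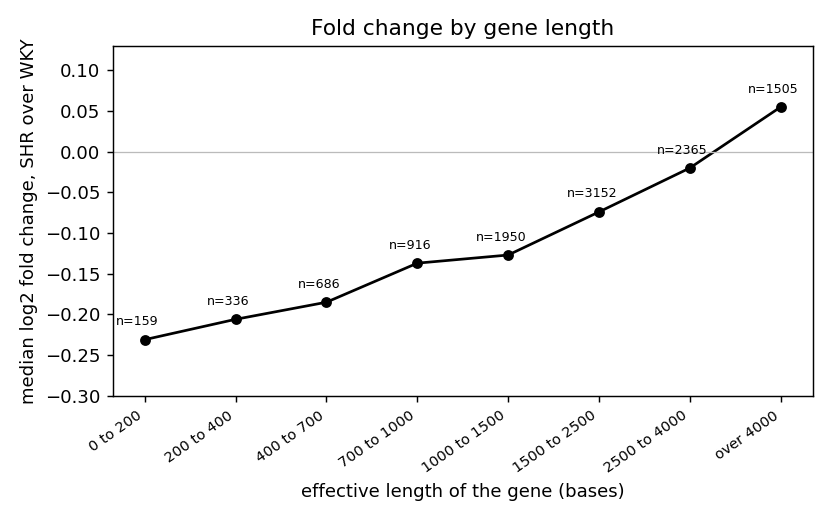
Median log2 fold change of SHR over WKY (vertical axis, on log2(FPKM + 1)) for the tested genes in 8 classes of effective length in bases (horizontal axis), with the number of genes at each point. The median rises from -0.23 in the shortest class to 0.06 in the longest.

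At a q-value under 0.05, the authors' deposited values gave 675 genes higher and 1128 lower in SHR, of 11762 genes. Among the genes tested here 1640 had such a q-value, and 1117 of the 1204 genes called here were among them with the same direction. The authors' deposited list of strongly changed genes holds 611 symbols, 176 higher and 435 lower in SHR, all at least 2-fold. Across genes, the authors' deposited log2 fold changes and those computed here had a Spearman correlation of 0.987.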

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

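A library was singled out where its gap to the nearest of its group made up most of the group's whole range, past Dixon's limit for 4 samples. This held for 18 of 254 group values examined, and chance alone gives about 1 in 20, or 12.7. WKY replicate 3 accounts for 7 of the 18, and no other library for more than 2.

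In WKY replicate 3 ribosomal protein genes made up 2.39% of the signal, against 2.99 to 3.08% in the other WKY libraries. Its scores were 0.227 for the circadian list (others -0.271 to -0.211), 0.062 for tight and adherens junctions (others -0.108 to -0.080) and 0.387 for tuft cell markers (others -0.131 to -0.049). Its FPKM was 0.9 for Mme (others 0.32 to 0.38), 44.67 for Nectin2 (others 38.61 to 39.31) and 109.88 for Vdr (others 95.68 to 97.03). SHR replicate 3 also stood apart in the ribosomal share, at 2.01% against 2.48 to 2.56%.

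In the remaining genes the library set apart was SHR replicate 4 for Cdx1 (141.49 FPKM, others 178.49 to 186.88) and Hmox1 (1.49, others 3.54 to 3.9). It was SHR replicate 2 for Kcnn4 (42.57 FPKM, others 33.28 to 34.66) and Alpi (0.02, others at 0), and SHR replicate 1 for Klf2 (0.24 FPKM, others 0.83 to 0.97) and Nfil3 (12.77, others 8.22 to 8.56). In WKY it was replicate 1 for Smoc2 (4.08 FPKM, others 5.91 to 5.98) and Cd36 (0.5, others 1.44 to 1.65), replicate 2 for Tspan13 (102.38 FPKM, others 83.85 to 86.61) and replicate 4 for Setd4 (0, others at 0.03).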

How the results depend on the processing

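All of the 85 called named genes reported here kept their direction in those of the 19 alternatives in which they were tested. Of these genes, 63 also kept their call in each such alternative. When a library was left out, the filter was applied again, and a gene that dropped out counted as kept. This holds for Cbr1, Cbr3, Setd4, Hsp90aa1, Fam78b, Zp2 and Ifit1, not tested without any of the SHR libraries. It also holds for Alpi, Pigz, Klf2, Neurod1 and Nkg7, not tested without any of the WKY libraries. The other 22 called genes lost the call in some alternative, 11 of them only when a library was left out. Of the 8 such fits, the call was lost in 7 for Fabp2, in 6 for F11r, Kcnn4, Pdia3, Per2, Prcp, Slc4a2 and Tmigd1, in 5 for Cd3g, Cdx1 and RT1-Da, in 4 for Aurka, Marveld2, RT1-Db1 and Sc5d, in 3 for Fdft1 and Relb, in 2 for Ephb3 and Slc10a2, and in 1 for Birc5, Marveld3 and Slc51a. Slc10a2 was tested only in the fits without a WKY library, since it fell below the filter in the others. The replicate block ended calls of Cdx1, Kcnn4, RT1-Da, RT1-Db1, Sc5d, Slc4a2 and Tmigd1, and the length correction those of Cd3g, RT1-Da, Slc4a2 and Tmigd1. Slc10a2 also lost its call with a pseudocount of 5, Per2 with 0.1, Pdia3 with quantile normalization and RT1-Da with median centring. Named-list genes without a call, other than Rgs2, were left out of this comparison, most of them after their values were seen. Alternatives for count data were not run, since no counts are at hand, and reads per library are unknown.

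The count of higher genes moved from 376 to 642 with quantile normalization, where fewer than the 828 lower genes were called (644). With the authors' q-values it was 675, of which 369 were called here too. Requiring at least 2-fold left 64 higher and 143 lower genes at an adjusted p under 0.05, and 66 and 159 under 0.1, by construction. Leaving out single libraries gave 191 to 550 higher genes and 440 to 1126 lower genes. Fewer samples and fewer tested genes are part of this, and the cause of the spread was not tested. The labels do not say whether the replicate numbers pair the samples. Residuals of same-numbered libraries correlated at -0.11, -0.04, 0.46 and -0.29. The libraries numbered 3 went together more than the others, so pairing or a shared batch is not settled. With the replicate block 395 genes were higher and 917 lower, and 12 lists passed.

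The 12 lists became 0 with an estimated correlation and 6 with fry (5 of the 12), which asks whether a list's genes move one way and not whether they differ from other genes; for both, the cause was not tested. Fry ended the calls of mitosis and S phase (0.0692), T and natural killer cells (0.0528), interferon (0.136), cholesterol synthesis (0.2), fatty acid oxidation (0.0692), junctions (0.13) and the circadian clock (0.371), and added xenobiotic metabolism as lower (0.0147). Other lists gained a call in single alternatives: colonocytes as higher with quantile normalization (0.0441), fibroblasts as higher without a filter (0.0111), and oxidative phosphorylation as lower without WKY replicate 3 (0.00581) or SHR replicate 1 (0.0118). Leaving out single libraries gave 11 to 13. Apart from the estimated correlation, goblet cell markers, bile acid and sterol handling and the unfolded protein response passed under every alternative. None of the 12 changed direction. Lists that had not passed changed the direction of the test, at these adjusted p: with genes below the median level left out, antimicrobial secretions 0.491, SHR traits 0.0729, stem cells 0.993 and xenobiotic metabolism 0.993; with fry, SHR traits 0.17, hypoxia 0.398, inflammatory cytokines 0.613, ion transport 0.757 and tuft cells 0.888; oxidative phosphorylation with quantile normalization 0.805 and the length correction 0.907; hypoxia with median centring 0.984, the replicate block 0.996 and short genes left out 0.996. Leaving out single libraries also changed it in some of the 8 fits, whose adjusted p ran over 0.345 to 0.968 (antimicrobial secretions), 0.557 to 0.953 (SHR traits), 0.238 to 0.891 (heat shock), 0.539 to 0.995 (hypoxia), 0.426 to 0.984 (inflammatory cytokines), 0.199 to 0.995 (macrophages), 0.308 to 0.968 (short-chain fatty acids) and 0.166 to 0.995 (tuft cells). For antimicrobial secretions these were the fits without a WKY library. In them Alpi, the member with the largest fall, was below the filter and left the list.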

Other observations

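The tests of crypt base and colonocyte shares, the exact permutation of list scores and the length correction with library medians kept were chosen after the result was seen, and the other length corrections were added after seeing the data, with bounds written before they were run. That 2 list means must differ by more than the SD of their members was also required after the result was seen. For shared symbol roots, the bound written for ruling the explanation out was met and was set aside after the result was seen, for the reason given below.

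Families of at least 5 tested genes with a common symbol root were scanned with camera (330 families, preset correlation, Benjamini-Hochberg adjusted), and 4 passed, all lower in SHR. With an estimated correlation none did (adjusted p = 0.992 for all 4). In the mast cell protease family all 5 tested members were lower in SHR (adjusted p = 0.00142, or 0.00396 with the length trend removed). Mcpt2, a protease of mucosal mast cells, went from 39.9 ± 7.12 to 14.04 ± 1.18 FPKM, Mcpt4 from 9.45 ± 3.64 to 1.47 ± 0.326 FPKM and Mcpt8 from 27.2 ± 2.41 to 18.5 ± 4.46 FPKM (SD, n = 4). In the RT1 family, the rat major histocompatibility complex, 18 of 24 members were lower and 2 higher (adjusted p = 3.62e-09). The class I gene RT1-A2 fell from 403.0 ± 38.2 to 80.5 ± 20.1 FPKM while RT1-A1 rose from 345.5 ± 44.8 to 936.8 ± 129.9 FPKM. The family pools class I and class II genes, which are not all near-identical. RT1 genes can have close relatives and differ between inbred strains, so reads can be assigned to another member than the one they came from. Ribosomal protein genes of the large subunit (2 of 47 lower, adjusted p = 0.00243) no longer passed with the length trend removed (adjusted p = 0.227). The Cd family shares only its naming scheme (12 of 37 lower, 2 higher, adjusted p = 0.046, or 0.11 with the length trend removed).

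Other family members singled out after their values were seen had calls of their own. Tlr5, the receptor for flagellin, rose from 3.83 ± 0.620 to 19.7 ± 5.90 FPKM (limma adjusted p = 1.31e-05), while the Tlr family did not pass (adjusted p = 0.0668). Hoxa10 and Hoxa9, which mark position along the gut, fell by 0.96 ± 0.17 and 0.92 ± 0.17 on the log2 scale (adjusted p = 0.00375 and 0.00435), in a family that also did not pass (adjusted p = 0.0593).

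More genes were lower than higher in SHR, 68.8% of 1204 calls. After the length trend of each library was removed 53.1% were lower, and after each library was centred on its median gene 56.9%, but both steps take out the difference between library medians and so set the balance themselves, which decides nothing about length or scaling. With the length trend removed and each library's median kept, 68% were lower (384 higher, 817 lower), with 53.4 to 73.2% when single libraries were left out. Gene length and scaling cannot be told apart from a strain effect here, since the range without single libraries spans the bound of 60% and depth is unknown. A biological excess of lower genes stays open and was not tested.

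Chance in the grouping was examined by splitting the 8 libraries into 4 and 4 in all 35 ways. For the 1204 called genes, the real split was the only 1 of 35 with as many, the highest of the others being 2. It was likewise 1 of 35 for the 376 higher and for the 828 lower genes, where no other split had more than 2 in a direction. This is the smallest share that 35 splits allow, so it argues against chance for these counts and does not exclude it. The other splits all mix the strains, which widens the spread within their groups and makes calls less likely. For the 12 called lists chance stays open, since 5 of the 35 splits, the real one included, called as many and another split called 15. With the strains' own libraries, the list scores did not overlap between strains for 12 of the 30 lists, 8 of them among the called ones, and the exact permutation p of such a list is 0.0286, the smallest possible (0.0715 adjusted).

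The lists of goblet cells, of mitosis and S phase and of T and natural killer cells were lower in SHR, and explanations besides regulation within cells were weighed. Gene length as the whole cause is argued against, since 83.7%, 91.6% and 89.3% of the lists' median log2 fold changes were left after the length trend was removed. A larger share of colonocytes in the SHR preparations, which would lower all other epithelial types alike, is argued against as the whole cause for goblet cells, because tuft cell markers had a mean log2 fold change of -0.05 ± 0.27 against -0.55 ± 0.48 for goblet cell markers (SD over 10 and 17 genes, permutation p = 0.0058, genes not being independent replicates), although enteroendocrine markers fell with goblet cell markers (mean -0.72, 10 of 11 negative) and colonocyte markers passed as higher with quantile normalization (adjusted p = 0.0441), so a part in it stays open. That argument is weak, since the gap of 0.5 only just exceeded the SD of 0.48, a bound set after the result was seen. Fewer crypt base cells cannot be told apart for the mitosis list, because stem cell and Wnt targets went both ways, with a mean of -0.26 ± 0.41 against -0.56 ± 0.13 (SD over 10 and 30 genes, permutation p = 0.0016, or 0.006 without the member called higher), a gap smaller than the stem cell members' own SD. For lymphocytes, the members' deviations within the strains correlated at 0.87 on average, above all 10000 random sets of the same size and level (percentile 100, 95th percentile 0.26), so the number of lymphocytes carried along may differ from preparation to preparation, and a strain difference in their number stays open.

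The strongest differences included neighbours in the gene order of the black rat, such as Cbr3 and Setd4. A hypothesis is that blocks of strain sequence or copy number differences underlie them. There were 6 adjacent pairs among genes called with at least 2-fold, against 1.31 on average in 10000 random reassignments (one-sided permutation p = 0.002). This met the bound written in favour for the genes that could be placed. All 6 pairs were of different symbol root, against 1.29 on average (one-sided permutation p = 0.001). Only 52.2% of the genes with at least 2-fold could be placed, in the order of another species. A minimum share of placed genes, which the written bound did not hold, was also required and was missed, so the question stays open. Reads shared between near-identical genes were tested by common symbol roots, which 71.4% of the 168 genes with at least 2-fold and 71.4% of the others had (Fisher's exact p = 1). The bound for ruling this out was met but set aside, since a root held by most genes does not single out near-identical ones, and no genome was at hand for a sequence comparison.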
